A study of Felis catus with 25 samples.

How the data were processed

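Polyadenylated RNA of 25 samples, 5 in each of 5 groups, was made into libraries from 200 ng of total RNA with a stranded TruSeq kit and sequenced on a NovaSeq instrument, per the labels' protocols. The submitters' processing notes name fastp 0.23.1, STAR 2.7.9a, Subread 2.0.1, featureCounts and Salmon 1.5.2, without the role of each. Genome build, annotation and strand setting were not given in the sources used here. The authors deposited 1 table of read counts per sample, with 13949 gene symbols and their raw integer counts and no header. All tables held the same symbols, 13111 of them with a count in any sample, and columns were assigned to samples by the sample titles in the labels. The RefSeq gene table of the cat (assembly F.catus_Fca126_mat1.0) was used only for names, neighbours and genomic spans of genes, and 13794 of the symbols were found in it. Rows of noncoding RNA families took at most 0.0182% of the counts of a library. Of the 642 genes of the fixed lists, 535 were in the files. The others, among them TAGLN, PKM, MKI67, KERA, NQO1 and HMOX1, were not analysed here.

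Counts were analysed in R 4.3.3 with edgeR 4.0.16. All 25 libraries were fitted together with TMM scaling and 1 mean per group, after edgeR's filter on expression (minimum count 10, minimum total 15), which left 10699 genes. Changes were tested with edgeR's quasi-likelihood F test for 9 comparisons, with no block for replicate number. P-values were adjusted by the Benjamini-Hochberg method (BH) over the tested genes, and a gene was said to rise, fall or change at an adjusted p under 0.05. Standard errors of log2 fold changes are the absolute log2 fold change over the square root of F. CPM are counts over the TMM-scaled library total in M.

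The 33 gene lists were written beforehand. Those with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, BH-adjusted over the lists. Camera asks whether a list moves more than the other genes. Its preset correlation between genes of 0.01 treats members as nearly independent. The p with a correlation estimated from the residuals of all 25 libraries is the stricter. The fry test, kept in the tables beside camera, asks whether members move at all without regard to other genes. The groups, comparisons, main tests, gene lists and 1st set of alternatives were chosen before the data were examined. So was the rule for named genes. For each main comparison it names ACTA2, MPC1, MPC2 and PPARG, and the 6 genes with the largest and the 6 with the smallest fold change with a mean of at least 10 CPM in the higher group and no overlap between groups (4 and 4 against FB). It adds up to 3 members of a called list in its direction and 2 against it, with the lowest p, and up to 2 of a list not called. Names outside the rule are marked, and some genes that the rule selects are not reported here.

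Where a group had 0 counts of a gene, the fold was given as a lower bound from a floor of 3 counts over the group, which lay between 0.023 and 0.0374 CPM. For 1 to 3 counts a ratio with a 95% counting interval was given. The TGFb1 response score of a library was the mean log2 CPM of genes at least 2-fold higher in TGFb than in FB, minus that of genes at least 2-fold lower, rescaled to 0 at the FB mean and 1 at the TGFb mean. Groups were compared by an exact permutation test. Covariances of comparisons that share libraries were set beside those of simulated unchanged groups, and overlaps beside those of independent lists and beside the same overlaps with the shared libraries split.

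The code was tested on simulated counts with known changes. In simulated TGFb against FB, edgeR found 84 of 100 genes changed 2-fold and 51 of 100 changed 1.5-fold, with 2 false calls among 9931 unchanged genes. In simulated UK against Trog with no change it called 0 of 10131. Depth was 14.8 to 25.2 M counts per library. Alternatives were DESeq2 1.42.0, limma voom, other scaling factors, library totals alone, stricter and no filters, fits of only the 2 groups compared, each library left out in turn, and a block for replicate number. Figures were drawn with matplotlib 3.10.9.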

Results

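Polyadenylated RNA was sequenced from cultured corneal fibroblasts of the domestic cat (Felis catus), the stromal cells that turn into contractile myofibroblasts under transforming growth factor beta 1 (TGFb1). The 25 libraries formed 5 groups of 5. FB held untreated fibroblasts at day 0, quiescent per the labels, and TGFb held cells after 2 days with TGFb1 at 1 ng/ml. In the other groups TGFb1 was taken away at day 2 and the cells received a drug until day 5. Trog received 7.5 uM troglitazone, a thiazolidinedione ligand of the nuclear receptor PPAR-gamma. TrogGW received the same dose of troglitazone with 10 uM GW9662, an antagonist of PPAR-gamma. UK received 30 uM UK-5099, an inhibitor of the mitochondrial pyruvate carrier, which is formed by the MPC1 and MPC2 proteins. Troglitazone and UK-5099 were thus used at different doses. The labels call the 5 libraries of a group biological replicates but do not say whether these were separate cultures or donors, so p-values measure only the spread between these libraries.

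The libraries held 14.8 to 25.2 M counts, with group means of 20.2 M (FB), 21.6 M (TGFb), 20.5 M (Trog), 19.5 M (TrogGW) and 20.7 M (UK). The 10 highest genes took 22.3% ± 1.2 of the counts in TGFb and 22.7% ± 3.76 in UK, but 10.9% ± 0.334 in Trog and 8.56% ± 0.452 in TrogGW (SD, n = 5). The number of genes with a count was highest in TrogGW, at 12054 ± 41.5, and 11203 ± 72.3 in TGFb. Of the markers of other cells in the files, 3 of 10 of corneal epithelium, 8 of 10 of corneal endothelium and 2 of 10 of melanocytes and Schwann cells passed the filter on counts. So did 6 of 14 of immune cells and 6 of 13 of vascular endothelium. UK replicate 5 stood apart. Its log2 CPM correlated with the other UK libraries at 0.852 to 0.868 across genes, against at least 0.988 for every other pair within a group, and it had the lowest total, 14.8 M. Many results that hinge on this library are named with the value without it. For comparisons that do not use the UK group, the reversal, the overlaps and GW9662, this alternative was chosen after seeing the data.

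**Figure D1:**
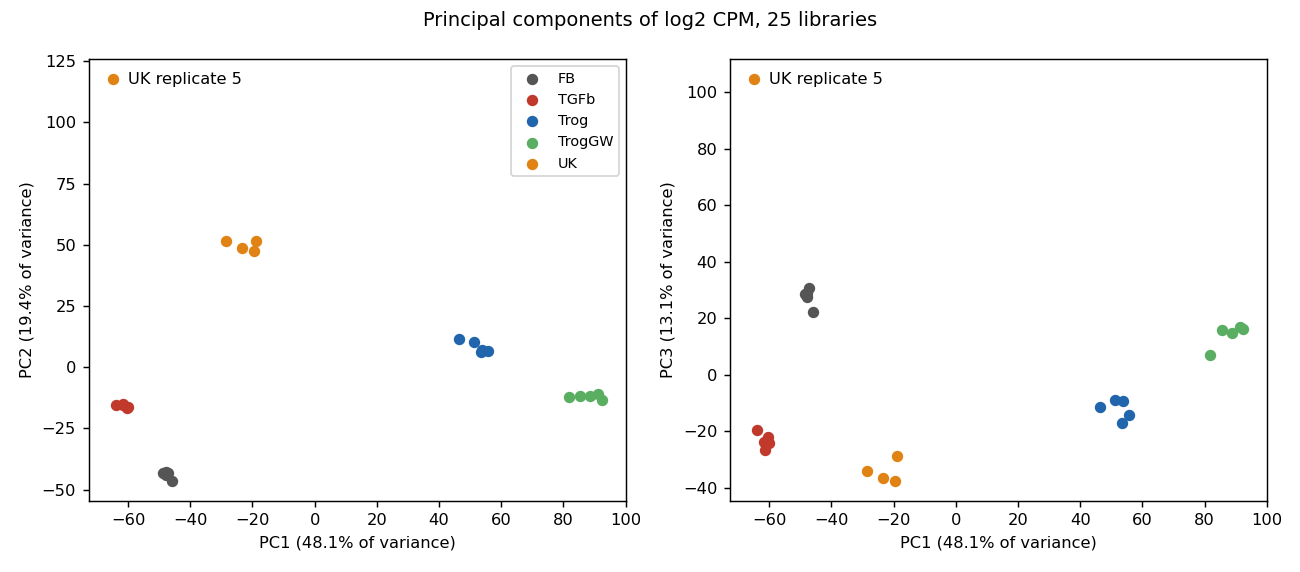
Each point is 1 library, placed by principal components of log2 CPM (PC1 against PC2 on the left and against PC3 on the right, with the percent of variance on each axis) and coloured by group. The libraries of each group lie together except UK replicate 5, which lies at 117.8 on PC2 and 104.8 on PC3, where no other library exceeds 51.61 and 30.68.

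Below, levels are mean CPM ± SD and changes are log2 fold changes ± SE, with n = 5 libraries per group. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg (BH) adjustment over 10699 genes. Those of gene lists are from limma's camera with BH adjustment over the lists, at a preset correlation between genes and, beside it, at a correlation estimated from the data. The largest rises and falls are those among genes with a mean of at least 10 CPM in the higher group and no overlap between the groups. Fixed gene lists are described by how many members rose or fell. Intervals and floors cover counting error only.

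The comparison of TGFb with FB set 2 days with TGFb1 beside untreated cells of day 0. No day-2 library without TGFb1 was analysed here, so the effect of TGFb1 and that of 2 days in culture could not be separated, here or in the genes and the score named after TGFb1 below. ACTA2, the smooth muscle actin gene that marks myofibroblasts, rose from 1942 ± 146 CPM to 9003 ± 427, a log2 fold change of 2.21 ± 0.477 (edgeR BH-adjusted p = 0.000638). Reads can be shared between ACTA2 and its close paralogs ACTG2 and ACTC1, so the levels of these actins are uncertain. Of the myofibroblast markers, 12 of 13 tested members rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 6.58e-08, and adjusted p = 0.0567 with an estimated correlation). They included TNC, which encodes the matrix glycoprotein tenascin C (4.38 ± 0.363), LMOD1, an actin filament nucleator of smooth muscle (2.27 ± 0.213), and CNN1, the contractile filament protein calponin (1.76 ± 0.126). Of the matrix assembly and crosslinking list, 13 of 20 tested members rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.00027, and adjusted p = 0.167 with an estimated correlation), with rises of the collagen lysyl hydroxylase PLOD2 (1.36 ± 0.0914) and the prolyl hydroxylase P4HA2 (1.18 ± 0.0947) and falls of the lysyl oxidases LOXL4 (-0.88 ± 0.169) and LOXL1 (-0.61 ± 0.169). LTBP2, a latent TGF-beta binding protein family member, rose by 5.03 ± 0.192.

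The largest rises were those of CILP, a cartilage matrix protein (8.02 ± 0.255), DPYS, a pyrimidine catabolic enzyme (8.02 ± 0.416), GABRP, a GABA receptor subunit (7.23 ± 0.356), the fibrillar collagen COL11A1 (6.77 ± 0.434), the matrix protein COMP (6.60 ± 0.299) and the NAD hydrolase CD38 (5.66 ± 0.501). GABRP reached 316 ± 54.3 CPM in TGFb against 2.1 ± 0.4 in FB. The largest falls were those of RRM2, a ribonucleotide reductase subunit (-4.98 ± 0.199), CDCA7 (-4.38 ± 0.245), the replication licensing regulator DTL (-4.35 ± 0.181), the mitochondrial carrier UCP2 (-4.30 ± 0.226), TCF19 (-4.02 ± 0.222) and ID1, a BMP-responsive inhibitor of differentiation (-4.02 ± 0.544). The highest adjusted p among these 12 genes was 2.16e-06 in edgeR with BH adjustment.

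Cell cycle genes fell. In S phase, 21 of 22 tested members fell and 0 rose (22 and 0 adjusted over the list alone, camera adjusted p = 1.03e-19, and adjusted p = 0.000518 with an estimated correlation), with falls of the replication helicase genes MCM4 (-3.41 ± 0.11) and MCM2 (-3.18 ± 0.107). Among G2 and M phase genes, 23 of 23 tested members fell and 0 rose (23 and 0 adjusted over the list alone, camera adjusted p = 4.76e-22, and adjusted p = 3e-04 with an estimated correlation), among them the spindle genes PRC1 (-3.11 ± 0.134), TPX2 (-2.60 ± 0.114) and KIF23 (-3.67 ± 0.194). The FB cells thus held more RNA of these genes than the TGFb cells. Whether all FB cells were quiescent, as the labels say of them, was not tested. For cholesterol synthesis and uptake, 15 of 19 tested members rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 2.38e-10, and adjusted p = 0.00402 with an estimated correlation), among them the sterol enzymes TM7SF2 (2.65 ± 0.167) and DHCR7 (1.57 ± 0.104). For fatty acid synthesis, 11 of 16 tested members rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.000104, and adjusted p = 0.108 with an estimated correlation), with rises of the desaturase FADS2 (2.72 ± 0.18) and FASN, the fatty acid synthase (1.82 ± 0.208). For glycolysis, 10 of 16 tested members rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.000125, and adjusted p = 0.0147 with an estimated correlation). ALDOC changed by 1.52 ± 0.102 and PFKFB4 by 1.71 ± 0.217; with library totals alone the glycolysis members were 4 higher and 4 lower.

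Of the hypoxia list, 12 of 17 tested members rose and 1 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.00063, and adjusted p = 0.0511 with an estimated correlation), and of the matrix metalloproteinases and inhibitors, 8 of 13 tested members rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.000362, and adjusted p = 0.00459 with an estimated correlation). ADAMTS5, an aggrecanase, changed by 2.76 ± 0.26. Of the inflammatory cytokines, 6 of 12 tested members rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0182, and adjusted p = 0.101 with an estimated correlation), among them PTGS2, the inducible prostaglandin synthase (4.63 ± 0.24). Of the ATF4 and integrated stress response genes, 10 of 16 tested members fell and 3 rose (10 and 3 adjusted over the list alone, camera adjusted p = 0.0371, and adjusted p = 0.313 with an estimated correlation), among them TRIB3, a stress-induced pseudokinase (-3.44 ± 0.283). Of the interferon response genes, 7 of 18 tested members fell and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.0216, and adjusted p = 0.0511 with an estimated correlation), among them the transcription factor IRF1 (-1.48 ± 0.118). The camera calls of the last 3 lists ended without UK replicate 5, with camera adjusted p = 0.0714, 0.0521 and 0.0714. The keratocyte (camera adjusted p = 0.0142, 0.0956 with an estimated correlation and 0.0827 without UK replicate 5) and smooth muscle lists (0.0124, 0.26 and 0.0521) also went up. The focal adhesion list went up too (camera adjusted p = 0.0216, adjusted p = 0.588 with an estimated correlation), with 8 members higher and 2 lower, but with library totals alone 2 were higher and 4 lower. Neither MPC1 (-0.11 ± 0.175, edgeR BH-adjusted p = 0.655) nor MPC2 (-0.31 ± 0.344, 0.512) passed the test. MPC1 did with library totals alone (-0.49, 0.0052), and MPC2 did without UK replicate 5 (-0.31 ± 0.0537, 7.59e-06) and in a fit of only the 2 groups (4.21e-06). PPARG had 3 counts in FB and 0 in TGFb.

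In all, 4089 genes changed, 1931 higher and 2158 lower, of which 1368 by at least 2-fold (623 higher and 745 lower). Without UK replicate 5, which enters through the shared estimate of the spread, 7124 genes changed, and 7087 in a fit of only the 2 groups. Higher genes made up 47.2% of the changes, and 13.9% with library totals alone, which moved the median log2 fold change of all genes by -0.375.

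**Figure D2:**
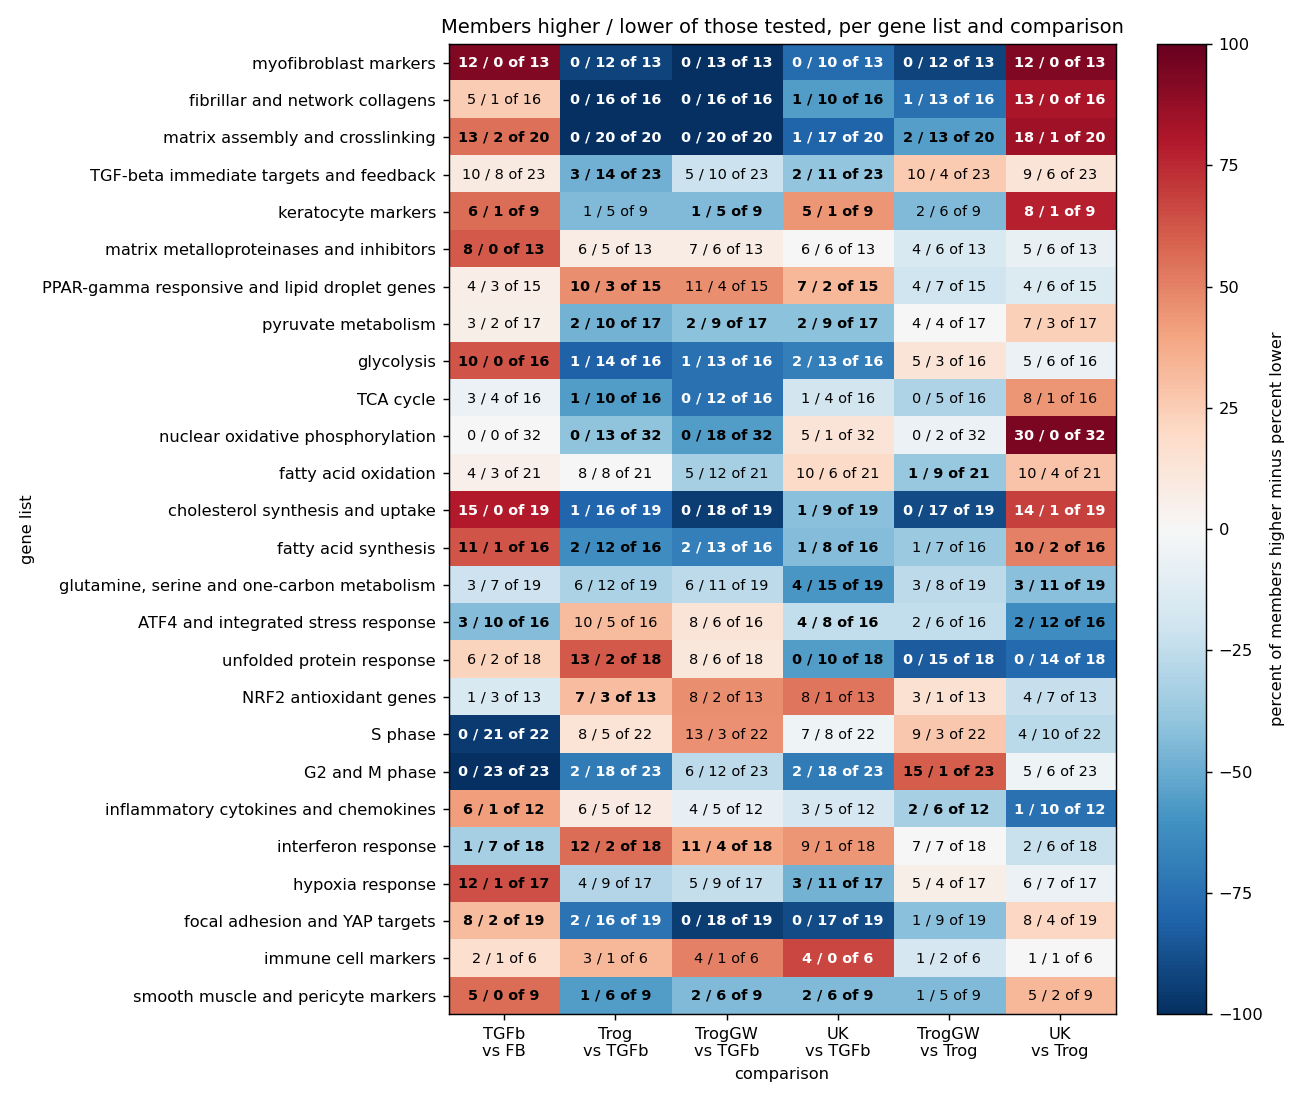
For each fixed gene list (vertical axis) and comparison (horizontal axis), the cell gives the members higher and lower of those tested, its colour gives the percent higher minus the percent lower, and bold marks lists called by camera at the preset correlation. Counts are with TMM scaling, and 15 lists are called for TGFb vs FB and 17 for Trog vs TGFb.

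The comparison of Trog with TGFb asked what followed when TGFb1 was replaced with troglitazone for 3 days. ACTA2 fell from 9003 ± 427 to 270 ± 73.6 CPM, a log2 fold change of -5.06 ± 0.542 (edgeR BH-adjusted p = 1.97e-08), below the 1942 ± 146 CPM of FB. Every tested collagen fell: among fibrillar and network collagens, 16 of 16 tested members fell and 0 rose (16 and 0 adjusted over the list alone, camera adjusted p = 3.27e-09, and adjusted p = 0.113 with an estimated correlation). COL1A1, the main chain of type I collagen, fell from 61380 ± 6120 to 1130 ± 270 CPM (-5.76 ± 0.249), as did COL3A1 (-7.31 ± 0.332) and COL15A1 (-4.13 ± 0.165). For matrix assembly and crosslinking, 20 of 20 tested members fell and 0 rose (20 and 0 adjusted over the list alone, camera adjusted p = 1.86e-12, and adjusted p = 0.0204 with an estimated correlation), including PLOD2 (-3.01 ± 0.097) and the lysyl oxidase LOXL2 (-3.76 ± 0.141). For the myofibroblast markers, 12 of 13 tested members fell and 0 rose (12 and 0 adjusted over the list alone, camera adjusted p = 1.44e-08, and adjusted p = 0.0467 with an estimated correlation), with the lowest p for CNN1 (-5.16 ± 0.147), the tropomyosin TPM1 (-4.30 ± 0.169) and LMOD1 (-4.39 ± 0.234). These 3 lists kept more members lower than higher under every scaling tried.

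FABP4, a fatty acid carrier induced by PPAR-gamma in adipocytes, had 0 counts in TGFb and 38.2 ± 5.6 CPM in Trog, at least 1020-fold higher. RSAD2, the interferon-induced antiviral protein viperin, was at least 545-fold higher and KNG1, which encodes kininogen, at least 360-fold higher. ATP6V0D2, a subunit of the proton pump of lysosomes and osteoclasts, was higher by 3420-fold (95% counting interval 614 to 135000) and the chemokine receptor CXCR4 by 692-fold (95% counting interval 191 to 5720). These bounds take 3 counts over a group as the floor for 0 counts. VAV3 rose by 8.11 ± 0.477. The largest falls were those of GABRP (-10.87 ± 0.444), the mechanosensitive target ANKRD1 (-10.20 ± 0.564), the growth factor IGF1 (-8.45 ± 0.462), endothelin EDN1 (-8.10 ± 0.432), TNC (-7.90 ± 0.427) and the actin ACTC1 (-7.46 ± 0.433). The highest adjusted p of these 12 genes was 1.43e-08 in edgeR with BH adjustment.

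Of the PPAR-gamma responsive and lipid droplet list, 10 of 15 tested members rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0182, and adjusted p = 0.0467 with an estimated correlation). PDK4, the kinase that turns off pyruvate dehydrogenase, had 1 count in TGFb and 487 in Trog, higher by 319-fold (95% counting interval 56.9 to 12600). ANGPTL4 rose by 2.59 ± 0.187 and the triglyceride lipase PNPLA2 by 0.97 ± 0.0916, whereas LPL, the lipoprotein lipase, went down (-1.51 ± 0.125). PPARG itself had 0 counts in both groups, so any level lay below about 0.0374 CPM in TGFb and 0.0245 in Trog if these counts take in all reads of the gene, which stays open. DGAT2, which makes triglycerides, rose by 4.74 ± 0.146 within the fatty acid synthesis list, of which otherwise 12 of 16 tested members fell and 2 rose (13 and 2 adjusted over the list alone, camera adjusted p = 0.00147, and adjusted p = 0.173 with an estimated correlation), among them ELOVL6 (-2.70 ± 0.161). For cholesterol synthesis and uptake, 16 of 19 tested members fell and 1 rose (16 and 1 adjusted over the list alone, camera adjusted p = 2.1e-07, and adjusted p = 0.0204 with an estimated correlation). DHCR7 changed by -2.91 ± 0.11 and TM7SF2 by -3.92 ± 0.177.

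For glycolysis, 14 of 16 tested members fell and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 8.52e-07, and adjusted p = 0.0098 with an estimated correlation), including lactate dehydrogenase LDHA (-2.78 ± 0.126), the lactate exporter SLC16A3 (-2.65 ± 0.11) and ALDOC (-2.27 ± 0.105). MPC1 went from 30.4 ± 1.46 to 20.8 ± 1.91 CPM (-0.54 ± 0.175, edgeR BH-adjusted p = 0.00958), but with library totals alone its value was 0.14. MPC2 did not pass (-0.38 ± 0.344, 0.348), and did without UK replicate 5 (-0.38 ± 0.0543, 2.15e-07) and in a fit of only the 2 groups (7.01e-06). Of pyruvate metabolism, 10 of 17 tested members fell and 2 rose (11 and 2 adjusted over the list alone, camera adjusted p = 0.0115, and adjusted p = 0.0427 with an estimated correlation). In the TCA cycle 10 of 16 tested members fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.0196, and adjusted p = 0.0467 with an estimated correlation), and in nuclear oxidative phosphorylation 13 of 32 tested members fell and 0 rose (9 and 0 adjusted over the list alone, camera adjusted p = 0.008, and adjusted p = 0.69 with an estimated correlation). With library totals alone these 3 directions turned, to 6 higher and 5 lower, 6 higher and 1 lower and 5 higher and 1 lower.

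Of the unfolded protein response list, 13 of 18 tested members rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.000478, and adjusted p = 0.157 with an estimated correlation), among them the chaperones DNAJB9 (2.31 ± 0.0833) and HYOU1 (1.82 ± 0.106) and HERPUD1 of endoplasmic reticulum degradation (3.08 ± 0.186). Of the interferon response genes, 12 of 18 tested members rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.0043, and adjusted p = 0.0204 with an estimated correlation). IRF1 changed by 3.35 ± 0.124 and the RNA sensor IFIH1 by 1.49 ± 0.102. Of the NRF2 antioxidant genes, 7 of 13 tested members rose and 3 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.0372, and adjusted p = 0.0787 with an estimated correlation), a call that ended without UK replicate 5 (adjusted p = 0.111), with GCLC, which starts glutathione synthesis, at 2.30 ± 0.102. Among G2 and M phase genes, 18 of 23 tested members fell and 2 rose (18 and 2 adjusted over the list alone, camera adjusted p = 0.000172, and adjusted p = 0.0787 with an estimated correlation). TOP2A changed by -2.02 ± 0.138 while TPX2 rose (1.78 ± 0.112). Of the focal adhesion genes, 16 of 19 tested members fell and 2 rose (16 and 2 adjusted over the list alone, camera adjusted p = 7.86e-05, and adjusted p = 0.252 with an estimated correlation). Filamin FLNA changed by -2.94 ± 0.189. Of the immediate targets of TGF-beta, 14 of 23 tested members fell and 3 rose (14 and 3 adjusted over the list alone, camera adjusted p = 0.00338, and adjusted p = 0.106 with an estimated correlation). TGFBI changed by -5.79 ± 0.269. The smooth muscle list also went down (camera adjusted p = 0.00453, 0.19 with an estimated correlation and 0.0562 without UK replicate 5).

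In all, 6699 genes changed, 3519 higher and 3180 lower, and 3177 by at least 2-fold. Of the changes, 52.5% were higher, and 83.2% with library totals alone, which moved the median of all genes by 0.684. No day-5 library without a drug was analysed here, so the effect of the drug and that of 3 days without TGFb1 could not be separated.

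**Figure D3:**
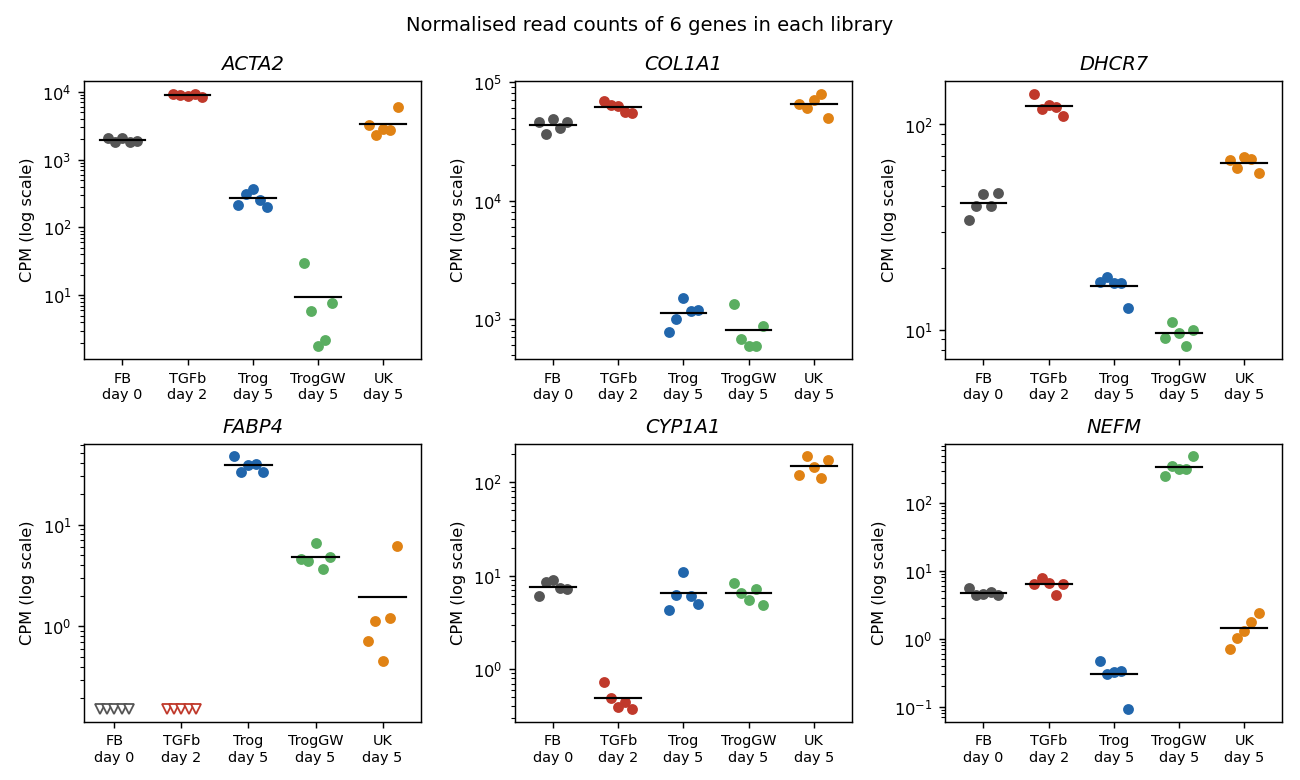
Normalised read counts (CPM, log axes) of 6 genes in each library by group. Points are libraries, horizontal bars are group means, and open triangles at the lower edge are libraries with 0 counts. ACTA2 averages 9003 CPM in TGFb, 269.9 in Trog and 9.379 in TrogGW, and FABP4 38.19 in Trog and 4.824 in TrogGW.

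The comparison of TrogGW with TGFb asked the same of troglitazone given with the PPAR-gamma antagonist. ACTA2 fell to 9.38 ± 11.5 CPM, a log2 fold change of -9.91 ± 0.672 (edgeR BH-adjusted p = 4.87e-12); its highest library, TrogGW replicate 1, held 29.45 CPM. Myofibroblast markers, collagens and matrix assembly genes fell again. For the myofibroblast markers, 13 of 13 tested members fell and 0 rose (13 and 0 adjusted over the list alone, camera adjusted p = 2.82e-10, and adjusted p = 0.0358 with an estimated correlation). LMOD1 changed by -7.98 ± 0.287 and TPM1 by -5.71 ± 0.181. For the collagens, 16 of 16 tested members fell and 0 rose (16 and 0 adjusted over the list alone, camera adjusted p = 9.22e-11, and adjusted p = 0.108 with an estimated correlation). COL3A1 changed by -10.24 ± 0.4 and COL1A1 by -6.24 ± 0.255. For matrix assembly, 20 of 20 tested members fell and 0 rose (20 and 0 adjusted over the list alone, camera adjusted p = 4.68e-13, and adjusted p = 0.0192 with an estimated correlation). The collagen chaperone SERPINH1 changed by -3.72 ± 0.119.

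RSAD2 was at least 565-fold higher than in TGFb. ARC, an immediate early gene of neurons, was higher by 2280-fold (95% counting interval 631 to 18800), GPR137C by 2610-fold (95% counting interval 469 to 103000), the vitamin D hydroxylase CYP24A1 by 2070-fold (95% counting interval 371 to 81700) and ATP6V0D2 by 1640-fold (95% counting interval 294 to 64800). The gap junction gene GJB2 rose by 10.63 ± 0.365, to 109 ± 14.8 CPM. GABRP was lower by 41800-fold (95% counting interval 7510 to 1650000), IGF1 was at least 707-fold lower, and ANKRD1 (-13.59 ± 0.672) and ACTC1 (-9.94 ± 0.481) were among the largest falls. The highest adjusted p of these genes was 1.22e-12 in edgeR with BH adjustment. PPARG had 65 counts in TrogGW, 6 to 28 per library, and 0 in TGFb, at least 13.3-fold higher.

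For cholesterol synthesis and uptake, 18 of 19 tested members fell and 0 rose (18 and 1 adjusted over the list alone, camera adjusted p = 9.56e-10, and adjusted p = 0.0175 with an estimated correlation). DHCR7 changed by -3.68 ± 0.114 and the sterol oxidase MSMO1 by -3.77 ± 0.127. For fatty acid synthesis, 13 of 16 tested members fell and 2 rose (13 and 2 adjusted over the list alone, camera adjusted p = 0.000838, and adjusted p = 0.163 with an estimated correlation). The acetyl-CoA synthetase ACSS2 changed by -2.28 ± 0.0921 and, against the list, DGAT2 by 4.33 ± 0.144. For glycolysis, 13 of 16 tested members fell and 1 rose (13 and 1 adjusted over the list alone, camera adjusted p = 3.75e-05, and adjusted p = 0.0192 with an estimated correlation). LDHA changed by -2.73 ± 0.126. Of pyruvate metabolism, 9 of 17 tested members fell and 2 rose (9 and 2 adjusted over the list alone), with camera adjusted p = 0.0182, and adjusted p = 0.0387 with an estimated correlation. Of the TCA cycle, 12 of 16 tested members fell and 0 rose (12 and 0 adjusted over the list alone), with camera adjusted p = 0.00602, and adjusted p = 0.0241 with an estimated correlation. Of nuclear oxidative phosphorylation, 18 of 32 tested members fell and 0 rose (16 and 0 adjusted over the list alone), with camera adjusted p = 0.00229, and adjusted p = 0.634 with an estimated correlation. These directions turned with library totals alone, to 8 higher and 5 lower, 6 higher and 0 lower and 3 higher and 0 lower. MPC1 fell (-0.52 ± 0.175, edgeR BH-adjusted p = 0.0121), but rose with library totals alone (0.34, edgeR BH-adjusted p = 0.0316). MPC2 did not pass (-0.69 ± 0.346, 0.0796), but did without UK replicate 5 (-0.69 ± 0.0548, 7.28e-13), in a fit of only the 2 groups (6.52e-10) and with limma voom (0.0474).

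Of the focal adhesion genes, 18 of 19 tested members fell and 0 rose (18 and 0 adjusted over the list alone, camera adjusted p = 1.04e-06, and adjusted p = 0.184 with an estimated correlation). The matricellular gene CCN1 changed by -3.14 ± 0.207. Of the interferon response genes, 11 of 18 tested members rose and 4 fell (11 and 4 adjusted over the list alone, camera adjusted p = 0.0175, and adjusted p = 0.0387 with an estimated correlation). The antiviral MX1 changed by 2.79 ± 0.154, and the call ended without UK replicate 5 (camera adjusted p = 0.0877). Of the keratocyte markers, 5 of 9 tested members fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.0368, and adjusted p = 0.163 with an estimated correlation, and 0.0836 without UK replicate 5), with lumican LUM at -3.73 ± 0.286 and decorin DCN at -1.42 ± 0.0998; with library totals alone they were 4 higher and 4 lower. The smooth muscle list went down (camera adjusted p = 0.00922, 0.237 with an estimated correlation and 0.0732 without UK replicate 5). Of the PPAR-gamma list, 11 of 15 tested members rose and 4 fell (11 and 4 adjusted over the list alone), and of the NRF2 list, 8 of 13 tested members rose and 2 fell (8 and 2 adjusted over the list alone). Neither was called (camera adjusted p = 0.0986 and 0.064), although PDK4 was higher by 297-fold (95% counting interval 53.1 to 11800) and GCLC by 4.10 ± 0.11.

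In all, 7421 genes changed, 4076 higher and 3345 lower, and 3926 by at least 2-fold. The share of higher genes was 54.9%, and 84.9% with library totals alone, a shift of the median by 0.851. The drugs and the 3 days without TGFb1 could not be separated here either.

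The comparison of UK with TGFb asked what followed when TGFb1 was replaced with the inhibitor of the pyruvate carrier. ACTA2 was 3408 ± 1460 CPM in UK, a log2 fold change of -1.40 ± 0.465 from TGFb (edgeR BH-adjusted p = 0.0151), and -1.70 ± 0.361 without UK replicate 5. Of the myofibroblast markers, 10 of 13 tested members fell and 0 rose (10 and 0 adjusted over the list alone, camera adjusted p = 0.000265, and adjusted p = 0.157 with an estimated correlation). TNC changed by -3.40 ± 0.347, CNN1 by -2.52 ± 0.13 and LMOD1 by -1.76 ± 0.209. For matrix assembly and crosslinking, 17 of 20 tested members fell and 1 rose (18 and 1 adjusted over the list alone, camera adjusted p = 2.61e-08, and adjusted p = 0.0505 with an estimated correlation). PLOD2 changed by -2.80 ± 0.0962, LOXL2 by -2.33 ± 0.133 and the transglutaminase TGM2 by -2.76 ± 0.166. For the collagens, 10 of 16 tested members fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 0.012, and adjusted p = 0.486 with an estimated correlation, and 0.0751 without UK replicate 5), with falls of COL15A1 (-1.85 ± 0.149) and COL6A3 (-1.55 ± 0.196) and a rise of COL11A1 (3.97 ± 0.29). COL1A1, named after its values were seen, stood at 65020 ± 11200 CPM in UK and 61380 ± 6120 in TGFb (0.08 ± 0.203, edgeR BH-adjusted p = 0.758).

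The largest rise was that of CYP1A1, a xenobiotic oxidase induced through the aryl hydrocarbon receptor, from 0.486 ± 0.142 to 148 ± 33.8 CPM (8.23 ± 0.301). It was followed by RASGEF1B (6.09 ± 0.227), RERG, a Ras-like growth inhibitor (5.54 ± 0.274), SLC15A3, a peptide transporter of lysosomes (5.45 ± 0.309), ACKR4, a scavenging chemokine receptor (5.37 ± 0.177), and ALDH3A1, a corneal crystallin and aldehyde dehydrogenase (5.29 ± 0.409). The largest falls reported here were those of GABRP (-8.12 ± 0.377), ANKRD1 (-5.68 ± 0.458), CASP14 (-5.33 ± 0.312), ALPK2 (-5.22 ± 0.222) and DISP3 (-4.91 ± 0.301). The highest adjusted p of these 11 genes was 3.66e-10 in edgeR with BH adjustment. The genes of the targeted carrier did not pass the main test. MPC1 was at 40.7 ± 19.6 CPM (0.42 ± 0.175, edgeR BH-adjusted p = 0.0506) and MPC2 at 90.8 ± 98.1 (0.81 ± 0.346, 0.055). Both means hinged on UK replicate 5, without which MPC1 was 0.07 ± 0.0669 (edgeR BH-adjusted p = 0.324) and MPC2 turned to -0.14 ± 0.0576 and passed (0.0342). With all libraries both passed with library totals alone (0.000921 for MPC1 and 0.0125 for MPC2) and with upper-quartile factors (0.0233 and 0.0408).

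For glycolysis, 13 of 16 tested members fell and 2 rose (13 and 2 adjusted over the list alone, camera adjusted p = 3.62e-07, and adjusted p = 0.00611 with an estimated correlation). SLC16A3 changed by -3.60 ± 0.115, LDHA by -2.69 ± 0.125 and the glycolytic regulator PFKFB3 by -2.75 ± 0.155. Of pyruvate metabolism, 9 of 17 tested members fell and 2 rose (9 and 4 adjusted over the list alone, camera adjusted p = 0.015, and adjusted p = 0.0505 with an estimated correlation). The dehydrogenase kinase PDK1 changed by -2.21 ± 0.0904 and pyruvate carboxylase PC by 1.21 ± 0.0874; with library totals alone its members were 6 higher and 6 lower. Of glutamine, serine and one-carbon metabolism, 15 of 19 tested members fell and 4 rose (15 and 4 adjusted over the list alone, camera adjusted p = 0.000256, and adjusted p = 0.00709 with an estimated correlation), with the mitochondrial folate enzymes SHMT2 (-2.19 ± 0.116), MTHFD2 (-1.83 ± 0.0876) and MTHFD1L (-1.77 ± 0.0686) down and glutamine synthetase GLUL up (1.70 ± 0.126). Of the ATF4 and integrated stress response genes, 8 of 16 tested members fell and 4 rose (8 and 4 adjusted over the list alone, camera adjusted p = 0.00699, and adjusted p = 0.157 with an estimated correlation). The serine pathway enzyme PHGDH changed by -2.20 ± 0.154 and asparagine synthetase ASNS by -1.73 ± 0.132. For the unfolded protein response, 10 of 18 tested members fell and 0 rose (10 and 0 adjusted over the list alone, camera adjusted p = 0.000687, and adjusted p = 0.157 with an estimated correlation). CALR changed by -1.47 ± 0.125. Of the hypoxia genes, 11 of 17 tested members fell and 3 rose (12 and 3 adjusted over the list alone, camera adjusted p = 0.00169, and adjusted p = 0.0735 with an estimated correlation). The disulfide oxidase ERO1A changed by -2.46 ± 0.123.

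Among G2 and M phase genes, 18 of 23 tested members fell and 2 rose (18 and 2 adjusted over the list alone, camera adjusted p = 6.61e-08, and adjusted p = 0.0265 with an estimated correlation). KIF23 changed by -4.57 ± 0.359 and TOP2A by -2.17 ± 0.141, and CDC20, with 1 count in UK, was lower by 183-fold (95% counting interval 32.4 to 7280). That count was in UK replicate 5, without which it was at least 53.8-fold lower. Of the focal adhesion genes, 17 of 19 tested members fell and 0 rose (17 and 0 adjusted over the list alone, camera adjusted p = 1.02e-06, and adjusted p = 0.157 with an estimated correlation). Paxillin PXN changed by -0.90 ± 0.0634. For cholesterol synthesis and uptake, 9 of 19 tested members fell and 1 rose (9 and 1 adjusted over the list alone, camera adjusted p = 0.0111, and adjusted p = 0.157 with an estimated correlation). DHCR7 changed by -0.92 ± 0.102. Of the immediate targets of TGF-beta, 11 of 23 tested members fell and 2 rose (11 and 2 adjusted over the list alone, camera adjusted p = 0.015, and adjusted p = 0.158 with an estimated correlation). TGFBI changed by -2.91 ± 0.233, while the receptor TGFBR2 rose (0.91 ± 0.0615). Of the keratocyte markers, 5 of 9 tested members rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0113, and adjusted p = 0.105 with an estimated correlation). DCN changed by 0.98 ± 0.0988 and the integrin-like ITGBL1 by 3.46 ± 0.365. Of the PPAR-gamma list, 7 of 15 tested members rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.0113, and adjusted p = 0.0505 with an estimated correlation). ANGPTL4 changed by 2.79 ± 0.188 and perilipin PLIN4 by 3.29 ± 0.351. Of fatty acid synthesis, 8 of 16 tested members fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.0113, and adjusted p = 0.265 with an estimated correlation). DGAT2 changed by -1.63 ± 0.168. Of the immune cell markers, 4 of 6 tested members rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.015, and adjusted p = 0.157 with an estimated correlation). The macrophage receptor CSF1R changed by 5.34 ± 0.311. Without UK replicate 5 these last 5 calls ended, at adjusted p = 0.0751, 0.146, 0.0751, 0.0638 and 0.128, as did that of the smooth muscle list (0.0079, 0.189 with an estimated correlation and 0.172 without it). Nuclear oxidative phosphorylation was not called (Up, camera adjusted p = 0.454), but without that library it was, in the other direction (Down, 0.00472).

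In all, 5408 genes changed, 2996 higher and 2412 lower, and 2170 by at least 2-fold. Leaving out UK replicate 5, 7657 changed, 334 of the calls were lost and 3 turned direction. A fit of only the 2 groups gave 3210. With library totals alone the share of higher genes went from 55.4% to 74.2% and the median moved by 0.231. As for troglitazone, the drug and the 3 days without TGFb1 could not be separated.

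The comparison of TrogGW with Trog asked what the PPAR-gamma antagonist changed at the same dose of troglitazone and the same day. ACTA2 was lower still with GW9662, at 9.38 ± 11.5 against 270 ± 73.6 CPM (-4.85 ± 0.542, edgeR BH-adjusted p = 1.21e-07). FABP4, named here after its values were seen, fell from 38.2 ± 5.6 to 4.82 ± 1.09 CPM (-2.98 ± 0.435, edgeR BH-adjusted p = 3.77e-05). For the myofibroblast markers, 12 of 13 tested members fell and 0 rose (12 and 0 adjusted over the list alone, camera adjusted p = 1.87e-07, and adjusted p = 0.161 with an estimated correlation). LMOD1 differed by -3.60 ± 0.252, the myosin light chain MYL9 by -2.15 ± 0.219 and TPM1 by -1.41 ± 0.151. Of the collagens, 13 of 16 tested members fell and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 1.16e-05, and adjusted p = 0.332 with an estimated correlation). COL3A1 differed by -2.94 ± 0.408 and COL16A1 by -1.62 ± 0.12. For matrix assembly, 13 of 20 tested members fell and 2 rose (15 and 2 adjusted over the list alone, camera adjusted p = 0.000554, and adjusted p = 0.317 with an estimated correlation), with the lysyl oxidase LOX at -2.35 ± 0.294 and SERPINH1 at -1.57 ± 0.109 down and PLOD2 up (1.19 ± 0.0912).

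NEFM, a neurofilament subunit of neurons, led the rises. It went from 0.306 ± 0.137 to 342 ± 87.3 CPM (10.08 ± 0.318), the synaptic pentraxin NPTX1 rose by 8.37 ± 0.387, ARC by 7.80 ± 0.343 and the neuropeptide gene NMB by 7.02 ± 0.391. PEG10, an imprinted gene derived from a retrotransposon, rose by 8.71 ± 0.37. TEX14, a gene of germ cell bridges, rose from 13.3 ± 2.67 to 2195 ± 730 CPM (7.37 ± 0.248). The largest falls besides ACTA2 were those of the protease ADAMTS15 (-5.70 ± 0.254), the transporters ABCA8 (-4.07 ± 0.289) and SLC45A2 (-3.87 ± 0.267), the transcription factor OSR2 (-3.75 ± 0.207) and the growth factor FGF1 (-3.67 ± 0.176). The highest adjusted p of these 12 genes was that of ACTA2. PPARG was at least 20.3-fold higher, with 65 counts against 0. Neither MPC1 (0.03 ± 0.175, edgeR BH-adjusted p = 0.918) nor MPC2 (-0.31 ± 0.344, 0.506) passed, and MPC2 did without UK replicate 5 (-0.31 ± 0.0542, 7.61e-06) and in a fit of only the 2 groups (0.000632).

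For the unfolded protein response, 15 of 18 tested members fell and 0 rose (15 and 0 adjusted over the list alone, camera adjusted p = 1.87e-07, and adjusted p = 0.132 with an estimated correlation). The disulfide isomerase PDIA4 differed by -1.91 ± 0.118, HYOU1 by -1.17 ± 0.104 and the stress sensor ATF6 by -0.98 ± 0.0858. For cholesterol synthesis and uptake, 17 of 19 tested members fell and 0 rose (18 and 0 adjusted over the list alone, camera adjusted p = 7.05e-07, and adjusted p = 0.0816 with an estimated correlation). MSMO1 differed by -1.24 ± 0.116. Of fatty acid oxidation, 9 of 21 tested members fell and 1 rose (9 and 1 adjusted over the list alone, camera adjusted p = 0.00926, and adjusted p = 0.319 with an estimated correlation). The carnitine transferase CPT1B differed by -1.87 ± 0.203 and CPT2 by -0.66 ± 0.0679. Among G2 and M phase genes, 15 of 23 tested members rose and 1 fell (15 and 1 adjusted over the list alone, camera adjusted p = 0.00103, and adjusted p = 0.254 with an estimated correlation). The kinase AURKA differed by 1.67 ± 0.171 and PRC1 by 1.23 ± 0.127, and KIF20A, with 0 counts in Trog, was at least 28.4-fold higher. Of the inflammatory cytokines, 6 of 12 tested members fell and 2 rose (6 and 2 adjusted over the list alone, camera adjusted p = 0.0369, and adjusted p = 0.254 with an estimated correlation), a call that ended without UK replicate 5 (adjusted p = 0.142), with the alarmin IL33 at -3.87 ± 0.265. Of the PPAR-gamma list, 7 of 15 tested members fell and 4 rose (7 and 4 adjusted over the list alone), and it was not called (camera adjusted p = 0.141). LPL fell (-2.41 ± 0.131). Of glycolysis, 5 of 16 tested members rose and 3 fell (5 and 4 adjusted over the list alone), and it was not called either (camera adjusted p = 0.395).

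In all, 4620 genes changed, 2438 higher and 2182 lower, and 1611 by at least 2-fold (1039 higher and 572 lower). The count was 7735 without UK replicate 5, which enters through the shared spread, and 7312 in a fit of only the 2 groups. With a filter at 5 CPM, 979 changed at least 2-fold. Among the changes 52.8% were higher, or 69.9% with library totals alone, which moved the median by 0.168. GW9662 without troglitazone was not analysed here.

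The comparison of UK with Trog set the carrier inhibitor beside troglitazone at day 5, at 30 and 7.5 uM. Contractile and matrix genes were higher with UK-5099. ACTA2 stood at 3408 ± 1460 against 270 ± 73.6 CPM (3.66 ± 0.508, edgeR BH-adjusted p = 1.38e-06). For the myofibroblast markers, 12 of 13 tested members rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 7.66e-07, and adjusted p = 0.106 with an estimated correlation). TPM1 differed by 3.68 ± 0.165 and CNN1 by 2.65 ± 0.132. Of the collagens, 13 of 16 tested members rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 7.66e-07, and adjusted p = 0.221 with an estimated correlation), with COL1A1 at 65020 ± 11200 against 1130 ± 270 CPM (5.85 ± 0.25). For matrix assembly, 18 of 20 tested members rose and 1 fell (18 and 1 adjusted over the list alone, camera adjusted p = 1.69e-06, and adjusted p = 0.116 with an estimated correlation). SPARC, a collagen-binding matricellular protein, differed by 4.72 ± 0.215. Of the keratocyte markers, 8 of 9 tested members rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.000355, and adjusted p = 0.0489 with an estimated correlation). LUM differed by 3.92 ± 0.288 and ALDH3A1 by 4.53 ± 0.358.

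The genes highest in UK against Trog were ACKR4 (7.83 ± 0.21), COL3A1 (7.19 ± 0.331), COL11A1 (6.56 ± 0.332), the small proteoglycans OMD (6.17 ± 0.548) and ASPN (5.89 ± 0.329) and the membrane protein TM4SF1 (5.90 ± 0.248). Those lowest were KNG1, lower by 1230-fold (95% counting interval 220 to 48500), RSAD2, lower by 620-fold (95% counting interval 212 to 3010), the adaptor GAB3 (-7.38 ± 0.29), ARFGEF3 (-6.81 ± 0.343), the teneurin TENM4 (-6.62 ± 0.377) and DGAT2 (-6.38 ± 0.164), with DGAT2 at 0.767 ± 0.258 against 65 ± 6.25 CPM. The highest adjusted p of these 12 genes was 1.1e-09 in edgeR with BH adjustment. MPC1 was higher in UK (0.96 ± 0.176, edgeR BH-adjusted p = 5.61e-05) and MPC2 too (1.19 ± 0.348, 0.00514). Both hinged in size on UK replicate 5, without which they were 0.62 ± 0.0666 (1.16e-09) and 0.24 ± 0.0571 (0.00036), and MPC2 did not pass with library totals alone (edgeR BH-adjusted p = 0.0739) or in a fit of only the 2 groups (0.0883).

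For the unfolded protein response, 14 of 18 tested members fell and 0 rose (14 and 0 adjusted over the list alone, camera adjusted p = 2.19e-07, and adjusted p = 0.0641 with an estimated correlation). DNAJB9 differed by -3.17 ± 0.0864, HYOU1 by -2.88 ± 0.111 and HSP90B1 by -2.72 ± 0.139. Of the ATF4 and integrated stress response genes, 12 of 16 tested members fell and 2 rose (12 and 2 adjusted over the list alone, camera adjusted p = 4.62e-05, and adjusted p = 0.0825 with an estimated correlation). ATF3 differed by -3.70 ± 0.143 and TRIB3 by -4.14 ± 0.29. Of glutamine, serine and one-carbon metabolism, 11 of 19 tested members fell and 3 rose (11 and 3 adjusted over the list alone, camera adjusted p = 0.00635, and adjusted p = 0.0489 with an estimated correlation). MTHFD2 differed by -2.19 ± 0.0886 and SHMT1 by -2.50 ± 0.157. Of the inflammatory cytokines, 10 of 12 tested members fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.0283, and adjusted p = 0.131 with an estimated correlation, and 0.0658 without UK replicate 5), with the adhesion molecule VCAM1 at -4.35 ± 0.462 and, against the list, IL33 at 4.38 ± 0.209. For cholesterol synthesis and uptake, 14 of 19 tested members rose and 1 fell (15 and 1 adjusted over the list alone, camera adjusted p = 1.55e-06, and adjusted p = 0.0489 with an estimated correlation). TM7SF2 differed by 3.13 ± 0.171 and DHCR7 by 1.99 ± 0.106. Of fatty acid synthesis, 10 of 16 tested members rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.0426, and adjusted p = 0.492 with an estimated correlation). FASN differed by 2.26 ± 0.211. For nuclear oxidative phosphorylation, 30 of 32 tested members rose and 0 fell (30 and 0 adjusted over the list alone, camera adjusted p = 0.000545, and adjusted p = 0.677 with an estimated correlation). The ATP synthase subunit ATP5F1A differed by 1.30 ± 0.239, and by 0.75 ± 0.0573 without UK replicate 5. Of glycolysis, 5 of 16 tested members rose and 6 fell (5 and 6 adjusted over the list alone), and of the PPAR-gamma list, 4 of 15 tested members rose and 6 fell (4 and 6 adjusted over the list alone). Neither was called (camera adjusted p = 0.99 and 0.415), although PDK4 was lower in UK (-3.36 ± 0.234).

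In all, 6534 genes changed, 3517 higher and 3017 lower, and 2943 by at least 2-fold. With UK replicate 5 left out, 8111 changed, 321 of the calls were lost and 2 turned direction. Scaling by library totals alone took the share of higher genes from 53.8% to 25.1% and moved the median by -0.449. Compound and dose differed together, so neither can be read alone.

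Against the untreated cells of day 0, Trog changed 6838 genes (3465 higher, 3373 lower), of which 3161 by at least 2-fold. ACTA2 was lower than in FB (-2.85 ± 0.49, edgeR BH-adjusted p = 2.24e-05). FABP4 was at least 1240-fold higher, and ATP6V0D2 was higher by 4160-fold (95% counting interval 746 to 164000), KNG1 by 1310-fold (95% counting interval 235 to 51800) and RSAD2 by 662-fold (95% counting interval 226 to 3210). The genes furthest below FB were the mitotic kinesin KIF20A (at least 1010-fold lower), the mitotic regulator CDC20 (-9.55 ± 0.355), DIAPH3 (-8.28 ± 0.385) and SHCBP1 (-8.11 ± 0.322). MPC1 was lower (-0.66 ± 0.175, 0.00229). MPC2 did not pass (-0.69 ± 0.345, 0.0819), but did without UK replicate 5 (-0.69 ± 0.0534, 5e-13), in a fit of only the 2 groups (3.08e-09) and with limma voom (0.0436). Higher genes made up 50.7%, and 68.2% with library totals alone, a shift of 0.308.

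In TrogGW 7461 genes differed from FB (3868 higher and 3593 lower, 3872 by at least 2-fold). ACTA2 (-7.69 ± 0.615), ANKRD1 (-10.68 ± 0.629), COL3A1 (-10.45 ± 0.402), CASP14 (-8.55 ± 0.387) and IL33 (-7.93 ± 0.27) were lower, and GJB2 was higher (10.65 ± 0.358). ARC was higher by 5540-fold (95% counting interval 993 to 219000), ATP6V0D2 by 1990-fold (95% counting interval 357 to 78700), GPR137C by 1590-fold (95% counting interval 439 to 13100) and PPARG by 16.1-fold (95% counting interval 5.28 to 80.3). MPC1 (-0.63 ± 0.175, edgeR BH-adjusted p = 0.00283) was lower, as was MPC2 (32 ± 1.28 against 64.2 ± 2.06 CPM, 0.0131), but with library totals alone neither passed (edgeR BH-adjusted p = 0.331 and 0.12). Higher genes made up 51.8%, and 73.9% with library totals alone, a shift of 0.476.

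In UK 6037 genes differed from FB (3206 higher and 2831 lower, 2664 by at least 2-fold), and 8396 without UK replicate 5, with 230 calls lost. COL11A1 (10.74 ± 0.444), the growth factor FGF7 (7.97 ± 0.463), CD38 (7.12 ± 0.499) and ITGBL1 (6.46 ± 0.454) were the genes furthest above FB. The mitotic genes KIF20A (-8.95 ± 0.326), KIF23 (-8.25 ± 0.295) and DIAPH3 (-8.14 ± 0.4) were lower, and CDC20 was lower by 2650-fold (95% counting interval 476 to 105000), at least 779-fold without UK replicate 5. ACTA2 (0.81 ± 0.46, edgeR BH-adjusted p = 0.137), MPC1 (0.30 ± 0.174, 0.142) and MPC2 (0.49 ± 0.344, 0.228) did not pass. ACTA2 did in a fit of only the 2 groups (0.0184), and without UK replicate 5 MPC2 was lower (-0.45 ± 0.057, 2.51e-08). Higher genes made up 53.1%, and 41.9% with library totals alone, a shift of -0.142.

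A score over the 1368 genes changed at least 2-fold in TGFb against FB was set to 0 at the mean of FB and 1 at the mean of TGFb. It was 0.7718 ± 0.102 in UK, 0.3505 ± 0.0254 in Trog and 0.1906 ± 0.0327 in TrogGW. Trog was lower than UK by a difference of -0.421 and higher than TrogGW by 0.16, and TrogGW lower than UK by -0.581. Each difference had p = 0.00794 in a two-sided exact permutation test over 252 arrangements, the smallest p this design allows, and 0.00794 after BH adjustment over the 3 tests. The part of the score from genes higher in TGFb than in FB was 0.1586 in Trog, 0.0838 in TrogGW and 0.6264 in UK, and that from lower genes 0.5421, 0.2971 and 0.9171. Of the 623 higher genes, 68.1% moved back in the direction of FB in Trog, 66.8% in TrogGW and 45.7% in UK, and of the 745 lower genes 54.8%, 66.7% and 35.7%. Moving back was not a return to the level of FB. Of the 623, 191 in Trog, 224 in TrogGW and 68 in UK lay past FB on the other side. Still on the TGFb side of FB were 266, 259 and 415. Of the 745, 169, 224 and 64 lay past FB, and 419, 373 and 537 were still on the TGFb side. The score averages over both kinds.

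**Figure D4:**
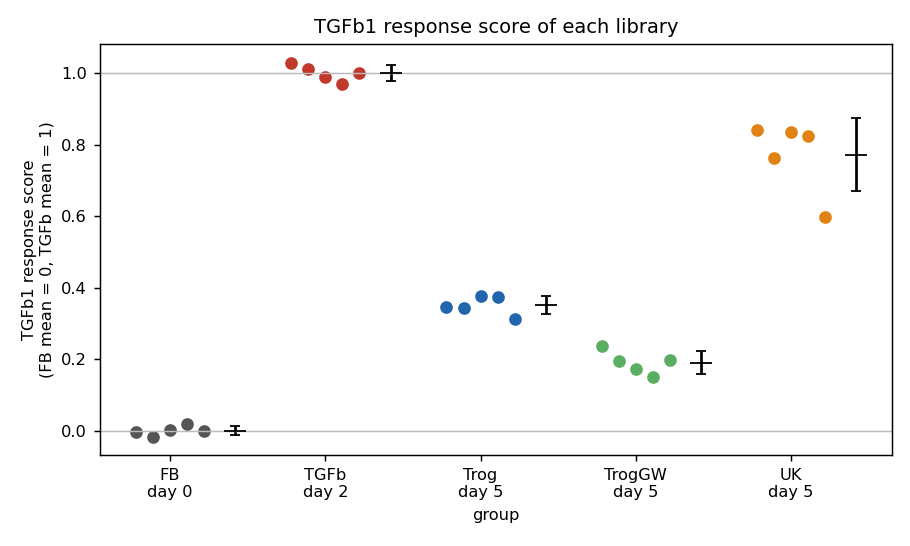
TGFb1 response score of each library (vertical axis, no unit, with the mean of FB at 0 and the mean of TGFb at 1) by group. Points are libraries and the bars beside them are mean ± SD (n = 5); every library of Trog and TrogGW lies below every library of UK, whose lowest, replicate 5, is at 0.598.

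In gene counts, 832 of these 1368 genes went back in Trog and 237 went further, 913 and 209 in TrogGW, and 551 and 333 in UK. These comparisons share the TGFb libraries. Independent lists of the same sizes gave 430.21 in Trog, 478.6 in TrogGW and 349.07 in UK. With UK replicate 5 left out, the counts in this order were 916, 999 and 629 of 1432 genes. Independent lists then gave 581.77, 620.43 and 508.41, a smaller excess. With the TGFb libraries split so that none was shared, the counts were 741 and 753 in Trog, 823 and 836 in TrogGW, and 437 and 472 in UK. Across genes the covariances of the 2 log2 fold changes were -0.462 (Trog), -0.599 (TrogGW) and -0.154 (UK), and in simulated unchanged groups -0.0256, -0.0258 and -0.0257. With library totals alone 1313 of 1788 genes went back in Trog, 1421 in TrogGW and 854 in UK, and independent lists gave 964.76, 1053.6 and 664.03.

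The responses of the day-5 groups against TGFb overlapped. Trog and TrogGW shared 5447 genes changed in the same direction (independent lists 2334.8, with split libraries 4634 and 4503), Trog and UK shared 3167 (1702.3, 2386 and 2481) and TrogGW and UK 3191 (1895.5, 2402 and 2558). Without UK replicate 5 the overlaps of Trog and TrogGW with UK were 5127 and 5132. Across genes, which are not independent replicates, log2 fold changes correlated at 0.83, 0.54 and 0.449 in these pairs, and simulated unchanged groups gave 0.522, 0.515 and 0.516. The covariances were 2.06, 0.832 and 0.833, and the simulated ones 0.0257, 0.0257 and 0.0258, differences of 2.04, 0.806 and 0.807. These overlaps include whatever 3 days without TGFb1 changed in every group.

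Of the 6699 genes of Trog against TGFb, GW9662 moved 1634 the opposite way and 1655 further the same way. Independent lists gave 1442.3 and 1450.4, and with the Trog libraries split the opposite counts were 1132 and 1198. Without UK replicate 5, 3073 moved the opposite way and 3235 further, where independent lists gave 3129.8 and 3132.4. The opposite count was thus not above that of independent lists there. The log2 fold changes of the antagonist and of troglitazone correlated at -0.00102 across genes, against -0.488 in simulated unchanged groups, with a covariance of -0.00141 against -0.0235, a difference of 0.0221. FABP4, DNAJB9 and HYOU1 were among the genes that moved the opposite way, and ACTA2, LMOD1, COL3A1 and DHCR7 among those that moved further.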

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

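Among the tests of this part, that of gene length and the values without UK replicate 5 were chosen after the result was seen. ACTA2, MPC1 and MPC2 each had a library far from the other 4 of its group. ACTA2 stood at 5958 CPM in UK replicate 5, against 2305 to 3235 in the other UK libraries, a gap of 0.745 of the group's range, and at 29.45 CPM in TrogGW replicate 1, against 1.754 to 7.656 (0.787). MPC1 stood at 75.75 CPM in UK replicate 5, against 31.57 to 32.45 (0.98), and MPC2 at 266.3, against 45.56 to 48.68 (0.986). Measures of whole libraries also stood apart by this gap, Dixon's test at its 95% critical value for 5 samples. They were the correlation of UK replicate 5 (0.984), FB replicate 2 (0.75) and TGFb replicate 4 (0.722) with their own groups, the share of counts in the 10 highest genes of TrogGW replicate 1 (0.743), FB replicate 2 (0.724) and UK replicate 5 (0.711), and the scaling factor of FB replicate 2 (0.74). In all, 11 of 50 groups of values had such a library, where chance gives about 1 in 20.

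Of 146 genes named in the text, without 10 named only for ideas tested afterwards, 39 had a library apart in UK, and in 35 of these it was UK replicate 5. The numbers were 15 in TGFb, 14 in FB, 15 in TrogGW and 11 in Trog, and chance gives about 1 in 20 groups. These genes are not independent of one another, since 1 unusual library moves many at once.

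UK replicate 5 correlated with the other UK libraries at 0.852 to 0.868, and had 10776 genes with a count where the others had 11209 to 11446. Lower depth was argued against: UK replicates 1 to 4, thinned to its total, still correlated with one another at 0.991 or more, and with UK replicate 5 at 0.866 or less. A mixture with or an exchange for cells of the other groups was argued against as well, since the best mixture of the group profiles (67.8% UK and 32.2% FB) correlated with this library at 0.858, where mixtures reached 0.996 or more in the other UK libraries. Loss of long genes stays open: the log2 ratio of this library to the rest fell with genomic span (Spearman correlation = -0.448 across genes), but in UK replicate 2 it was -0.283, so what such a trend means for 1 library cannot be told apart from ordinary variation. No biological explanation was tested, because the labels give this library the same treatment as the others.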

How the results depend on the processing

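Leaving out UK replicate 5 for the reversal, the overlaps, GW9662 and comparisons of other groups was chosen after the result was seen, and the other alternatives beforehand. All 25 counts of genes, reversals and overlaps stayed within 1.5 times with DESeq2, and so did the 18 counts of genes with limma voom, RLE and upper-quartile factors. Fits of only the 2 groups compared gave 7087 genes for TGFb vs FB, 3210 for UK vs TGFb and 7312 for TrogGW vs Trog, and a filter at 5 CPM left 979 genes changed at least 2-fold in TrogGW vs Trog, by testing fewer genes. With library totals alone the reversal counts were 1313 (Trog), 1421 (TrogGW) and 854 (UK), MPC1 turned to 0.14 in Trog vs TGFb (edgeR BH-adjusted p = 0.37) and to 0.34 in TrogGW vs TGFb (0.0316), and of 286 values of named genes 277 kept direction and side. The cause was not tested, but this scaling moved the median of all genes by 0.684 and 0.851 there. A minimum of 2-fold in both comparisons left overlaps of 2470 (Trog and TrogGW), 1154 (Trog and UK) and 1178 (TrogGW and UK), and 438 genes moved the opposite way by GW9662. With an estimated correlation 5, 8, 7, 3, 0 and 3 lists were called in the main comparisons from TGFb vs FB to UK vs Trog, against 15, 17, 13, 18, 8 and 11 at the preset one. For TrogGW vs Trog the 0 compares with 9 lists by camera with library totals alone. With each library left out in turn, genes changed ranged from 3657 to 7124 in TGFb vs FB and from 4176 to 7735 in TrogGW vs Trog, where the highest counts were without UK replicate 5. Without that library the overlaps of Trog and TrogGW with UK were 5127 and 5132 (independent lists 3101.1 and 3293.8). GW9662 then moved 3073 genes the opposite way (3129.8). Nuclear oxidative phosphorylation in UK vs TGFb turned down without UK replicate 5 (-2.326 as the signed -log10 of the camera adjusted p). Its highest adjusted p over the libraries left out gave 0.3027 on that scale. MPC1 in UK vs TGFb, at edgeR BH-adjusted p = 0.0506, also passed with DESeq2 (0.0482) and the filter at 5 CPM (0.0431). Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.187 to 0.328, and in 0 of 10 pairs of groups was every correlation over 0.1. With a replicate block the 25 edgeR counts and the 286 values of named genes kept direction and side, and 179 of 180 list results did; interferon response in UK vs TGFb passed with it (camera adjusted p = 0.0433). The exact sign-flip test with replicate block gave the same score differences (-0.421, 0.16 and -0.581) at p = 0.0625, the smallest its 32 patterns can give, which cannot pass 0.05. Depth limits what a count of 0 excludes, from 0.023 CPM in TrogGW to 0.0374 in TGFb.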

Other observations

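In this part, the tests of scaling and of opposition by GW9662, that of the PPARG counts, the values without UK replicate 5 and the other splits of the samples were chosen after the result was seen.

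Gene groups that camera did not call held single genes with large changes. LMNB1, the nuclear lamin lost in senescent cells, fell in every day-5 group against TGFb, with log2 fold changes of -4.57 ± 0.129 in Trog, -4.24 ± 0.127 in TrogGW and -1.84 ± 0.114 in UK (edgeR BH-adjusted p = 4.27e-12 or lower), while its list of p53 and senescence genes was not called, at camera adjusted p = 0.517, 0.827 and 0.818. CPT2, of mitochondrial fatty acid import, fell too (-1.62 ± 0.0688, -2.28 ± 0.0704 and -1.38 ± 0.0684 in the same groups), in a fatty acid oxidation list that was not called there (0.746, 0.0707 and 0.61). PPARGC1B, a coactivator of mitochondrial biogenesis, rose by 2.00 ± 0.263 in Trog against TGFb and was lower when GW9662 was added (-1.88 ± 0.25), and MMP11, a stromal metalloproteinase, followed with 2.34 ± 0.139 and -1.67 ± 0.133. ADAMTS5 was lower in UK than in Trog (-5.40 ± 0.271). Mitochondrially encoded genes took at most 0.000913% of the counts of a library, and 4 of the 13 could be tested.

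Contractile and matrix genes were lower still when the antagonist was added to troglitazone. Of the 49 members of the myofibroblast, collagen and matrix assembly lists tested, 48 fell in Trog against TGFb and 38 in TrogGW against Trog, and 37 fell in both. Of the 38, 34 stayed lower with library totals alone, so TMM scaling was argued against as the cause. Of the 48, 3 were higher in TrogGW than in Trog, which restates the pattern and decides nothing about its origin. An effect of GW9662 apart from PPAR-gamma stays open as a hypothesis, untested because no group received GW9662 alone.

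FABP4, a target of PPAR-gamma, had 4674 counts in Trog, where PPARG had 0. Another PPAR receptor may act in its place: PPARD had 62.7 CPM ± 2.87 in Trog, but also 56.2 ± 4.98 in TGFb, where FABP4 had 0 counts, so its presence alone does not account for FABP4. PPARA rose from 1.57 ± 0.19 CPM in TGFb to 7.05 ± 1.5 in Trog (2.15 ± 0.268, edgeR BH-adjusted p = 2.21e-07), and had 7.6 ± 0.804 in TrogGW and 7.1 ± 3.12 in UK. Whether the PPARG counts miss reads of the gene stays open: their highest group total was 65, in TrogGW, with 6 to 28 per library. The PPAR-gamma protein was not analysed here.

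CYP1A1 and ALDH3A1 were among the 6 largest rises named for UK, and a candidate explanation is activity of the aryl hydrocarbon receptor. Of its 3 other targets tested, 2 were higher in UK than in TGFb, TIPARP (0.75 ± 0.219, edgeR BH-adjusted p = 0.00607) and NFE2L2 (0.45 ± 0.0668, 4.59e-06), while AHRR did not pass (0.80 ± 0.352, 0.0604). AHRR did pass with library totals alone (0.0164), with upper-quartile factors (0.0442) and without UK replicate 5 (1.10 ± 0.0705, 1.78e-14). TIPARP did not pass in a fit of only the 2 groups (adjusted p = 0.104), and without UK replicate 5 it did (0.99 ± 0.0775, 1.98e-12). As a group, smaller than the 5 members asked of the lists, these targets had a camera p of 0.162 (direction up, 0.216 adjusted over the 4 gene group tests of this part), and 0.0109 without that library. With so few targets the hypothesis stays open.

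NEFM, ARC and NPTX1 rose when GW9662 was added, and other neuronal genes may rise with them. Of 14 such genes listed before the test, 5 could be tested and 3 were higher, ELAVL3 (6.11 ± 0.508), NEFL (2.35 ± 0.738) and MAP2 (2.02 ± 0.174). Camera gave p = 0.0127 for the group, with adjusted p = 0.0508 over the 4 gene group tests of this part, and the p was 0.0194 with an estimated correlation and 0.0138 without UK replicate 5. Neurons as a source were not tested. The hypothesis stays open, and rests on 5 genes listed after NEFM was seen.

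ATP6V0D2, a subunit of the lysosomal proton pump, rose in both troglitazone groups, and a rise of lysosomal genes as a group may go with it. In Trog against TGFb 14 of 25 tested lysosomal genes were higher and 5 lower (camera p = 0.049, adjusted p = 0.098 over the 4 tests, p = 0.178 with an estimated correlation and p = 0.0697 without UK replicate 5), led by GPNMB (4.27 ± 0.205), SQSTM1 (2.82 ± 0.206) and NPC1 (1.57 ± 0.167), which leaves the hypothesis open. In TrogGW against TGFb 7 were higher and 11 lower (camera adjusted p = 0.334 over the 4 tests, direction down), against such a rise there, although SQSTM1 (4.55 ± 0.223) and GPNMB (2.96 ± 0.195) were higher.

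Other splits of the 10 libraries of each comparison into 5 and 5 were tested, 100 of the 126 possible, with only those libraries in the fit. In every comparison 1 of the 100 splits, the real one, gave as many genes. Every other split put libraries of both groups into each arm, which raises the spread within arms and lowers the adjusted counts. The splits thus show only that the real grouping gave the most genes of those tried, and cannot exclude chance. The real and the highest other counts in edgeR were 7087 and 0 for TGFb against FB, 8454 and 0 for Trog against TGFb, 8993 and 0 for TrogGW against TGFb, and 3210 and 0 for UK against TGFb. They were 7312 and 0 for TrogGW against Trog, 4375 and 1 for UK against Trog, 8492 and 0 for Trog against FB, 8950 and 0 for TrogGW against FB, and 4034 and 966 for UK against FB. At an unadjusted p under 0.05 the highest other counts were 3633, 3050, 2973, 2509, 3767, 2282, 3365, 3277 and 3587 in this order, and no other tool was run on the splits.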
